A study of Mus musculus with 30 samples.

How the data were processed

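The series measured messenger RNA in YUMM1.7 mouse melanoma tumours grown under the skin from 5 clones, 2646TN, 2646R, 14559TN, 14559R and 13TN. The clone 13TN carries the word Depleted in its sample titles. Each clone was grown untreated or with RAFi/MEKi, with 3 tumours per group, which gives 10 groups and 30 libraries. Per the labels' protocols, the clones were isolated with CaTCH barcodes, the tumours were dissociated with collagenase, and live GFP-positive cells were sorted after staining for CD45. Libraries were made with the Lexogen QuantSeq 3′ mRNA kit, so a count reflects reads near the 3′ end of a transcript. The labels do not spell out TN and R, and these letters are used here only as names.

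Per the submitters' processing notes, the authors aligned reads with STAR 2.6.0c to GRCm38 and made the deposited counts with featureCounts 1.6.2 (paired, stranded). The unit of the deposited values is the count of reads per gene, per the file headers and the submitters' processing notes. All values in the files were whole numbers of 0 or more. The files held 54532 features per library, of which 54409 had a symbol and 25894 had at least 1 count in any library. Gene coordinates are those of GRCm38, and 53499 features had the same span as in GENCODE vM21.

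Totals ran from 3022801 to 5278453 counts per library, with a median of 4042893. Between 14669 and 17234 genes had at least 1 count in a library, with a mean of 16161. Spearman correlations between libraries of a group were 0.962 to 0.985. The chi-square per degree of freedom of a replicate pair was 3.29 to 17.8, against a value of 1 for counting error alone, so the libraries differed by more than counting error. The labels give every tumour its own code, so the replicate numbers are only names and no pairing was used.

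All tests on raw counts were run in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group, which left 13286 genes, and libraries were scaled with TMM factors. A single quasi-likelihood fit with robust dispersion and 20 residual degrees of freedom held the 10 groups, and the biological coefficient of variation was 18.2%. The 14 comparisons were contrasts of that fit: the response of each of the 5 clones, the mean response over the 5 clones, R against TN in each pair untreated and treated, the mean of the untreated 2646TN and 14559TN groups against untreated 13TN, and 3 differences between responses. The differences were 2646R minus 2646TN, 14559R minus 14559TN, and the mean of 2646TN and 14559TN minus 13TN. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes of a comparison. In all 14 comparisons the spread was that between tumours within a group, so no p-value covers the spread between clones. Levels are CPM with TMM factors, as mean ± SD over the libraries of a group. A log2 fold change is followed by its standard error, taken as the absolute log2 fold change over the square root of F.

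Where the lower group had 0 counts, the fold is given as at least the value reached with a floor of 3 counts over that group's libraries. Where it had 1 to 3 counts, the ratio is given with a 95% interval from the Poisson limits of the lower count. These intervals cover counting error only. No such bound or interval was computed for the mean response or for the differences between responses. There the size of a log2 value is uncertain where a group had few counts or none. Principal components were computed on log2 CPM with a prior count of 2, for the 1000 genes with the largest variance.

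A total of 34 gene lists were written before the data were examined: MAPK output, RAF-MEK-ERK components, DNA replication, mitosis, pigment cell differentiation, neural crest and glial, mesenchymal and invasive, receptor tyrosine kinases and ligands, type I interferon response, interferon gamma response, MHC class I presentation, MHC class II presentation, cholesterol synthesis, oxidative phosphorylation, glycolysis and hypoxia, ATF4 and unfolded protein response, NF-kappaB and inflammatory, p53 targets, BCL2 family, lysosome, YAP and TEAD targets, Wnt beta-catenin targets, drug efflux transporters, dissociation stress, and markers of macrophages, neutrophils, lymphocytes, endothelium, fibroblasts, pericytes and smooth muscle, keratinocytes, skeletal muscle, adipocytes and erythroid cells. The lists were written from general knowledge and were not taken from a database. Set tests used camera of limma 3.58.1 on the same fit with a preset correlation of 0.01, adjusted over the lists within a comparison, and were repeated with a correlation estimated from the residuals. Members were also counted as called over all genes and with p adjusted over the list alone. The 29 lists with at least 3 tested members were set-tested, a minimum chosen after the files were seen. The summed CPM of the other 5 lists is given instead.

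Genes named by size had an adjusted p under 0.05, a mean of at least 5 CPM in the higher group, no overlap of the log2 CPM ranges of the groups, and a plain symbol (not Gm with digits, Rik or a pseudogene suffix). For the mean response the range rule was replaced by the same sign in all 5 clones. For 2646TN and 14559TN against 13TN the ranges of 6 and 3 libraries had to be apart. The differences between responses had no range rule. The largest 10 per direction were taken for the mean response, R against TN untreated and TN against 13TN, and the largest 3 per direction elsewhere. Up to 4 members with the smallest p per called list and a panel of 12 genes (Dusp6, Spry4, Etv4, Ccnd1, Mki67, Mitf, Sox10, Axl, Ngfr, B2m, Ptprc and 1 that is not reported here) were tabulated as well, and text examples were drawn from these. Ngfr did not pass the low-count filter.

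Except for that minimum of 3 tested members, the choices above, the comparisons, the lists, the naming rule and these alternatives were fixed before the data were examined: median-of-ratios size factors in edgeR, a DESeq2 1.42.0 Wald test on the same genes, no low-count filter, only the groups compared in the fit, the L or R letter that ends the tumour code as a covariate, an estimated correlation for camera, and leaving out each library in turn. A covariate for the mean log2 CPM of the tested macrophage markers was added after the data were examined, as was leaving out each library for the list tests and the sharing counts. Sharing between comparisons was compared with the count for independent lists, the product of the 2 list sizes over the number of tested genes.

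Group labels were reassigned in splits. For a comparison of 3 libraries with 3, all 10 splits of the 6 libraries were run. For the comparisons over more groups, 100 splits were drawn, the real grouping included. These kept the group sizes and exchanged treatment labels only within a clone, or, for 2646TN and 14559TN against 13TN, group labels among the 9 untreated libraries. The code was tested on simulated data with 12787 genes. There edgeR called 71% of 100 genes changed 2-fold and 99% of 100 genes changed 4-fold, with 7 of 12567 unchanged genes called, and DESeq2 called 73%, 99% and 13. Camera gave a p of 5.07e-16 for a set of 20 genes raised 1.5-fold and a p under 0.05 for 0 of 100 unchanged sets. The simulated genes were drawn independently of each other, so these values do not test camera on lists of correlated genes.

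The reads were not used here, so barcodes, mutations and splicing were not analysed, and no cell type fractions were estimated. No library was left out of the main results. Clone and treatment of each library were taken from its labels, and the size, age and time under treatment of the tumours were not used here.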

Results

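Messenger RNA was measured in 30 subcutaneous YUMM1.7 melanoma tumours by sequencing of transcript 3′ ends. The tumours came from 5 clones, the pairs 2646TN and 2646R and 14559TN and 14559R and the single clone 13TN, each grown untreated or with RAFi/MEKi. Each of the 10 groups held 3 tumours, and GFP-positive live cells had been sorted before lysis. A library held 3022801 to 5278453 counts (median 4042893) with a mean of 16161 genes detected, and 13286 genes were tested. The comparisons, gene lists, naming rule and thresholds were fixed before the data were examined, except the minimum of 3 tested genes for a list test. All intervals given with ratios cover counting error only.

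Untreated and treated tumours of a clone lay apart on the first 2 principal components except in 14559R. There treated replicate 3 (PC1 43.9) lay among the untreated libraries (PC1 34.1 to 46.2). Treated replicates 1 and 2 (22.8 and 28.5) lay below them. The first component held 39.0% of the variance of the 1000 most variable genes and the second 23.7%. Treated 14559TN and 13TN libraries lay lowest on the first component (-53.2 to -44.1), and the 2646R and 14559R libraries lay above all others (17.7 to 46.2). The 2646 clones lay at the low end and the 14559 clones at the high end of the second component. Spearman correlations between libraries of a group were 0.962 to 0.985.

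**Figure D1:**
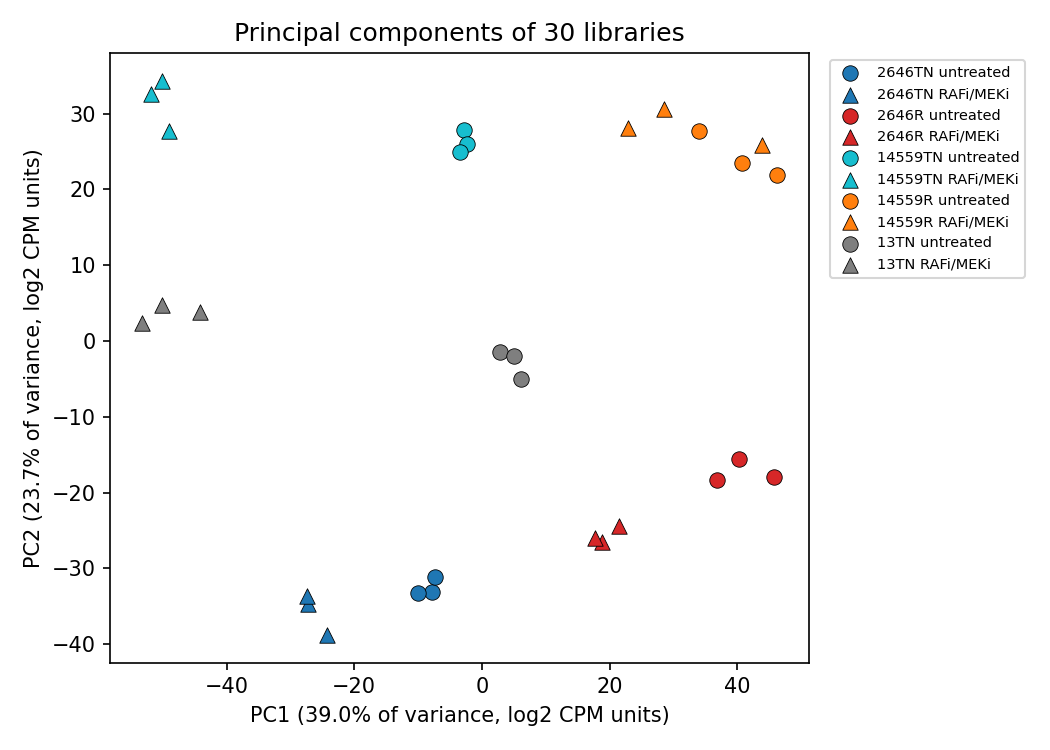
Position of the 30 libraries on the first component (39.0% of variance) and the second (23.7%), in log2 CPM units. Circles are untreated and triangles RAFi/MEKi tumours, with 1 colour per clone. Of the 14559R triangles 1 (PC1 43.9) lies among the 14559R circles (34.1 to 46.2), and the others (22.8 and 28.5) lie below them.

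The first question was what RAFi/MEKi changed in 2646TN. Treated tumours had lower transcripts of cholesterol synthesis and of glycolysis and hypoxia. Ogn, a matrix proteoglycan gene, rose from 0.936 ± 0.499 to 57.4 ± 34.6 CPM (n = 3 each). Acta2, which encodes smooth muscle actin, rose from 14.4 ± 3.87 to 406 ± 225 CPM. It belongs to the pericyte and smooth muscle markers, whose summed level went from 24.6 ± 1.85 to 414 ± 227 CPM (list not called, camera adjusted p = 0.0502). Acta2 alone held nearly all of the treated sum, so this rise was that of 1 gene and not of the markers as a group. Summed fibroblast markers went from 5672 ± 1109 to 10028 ± 3924 CPM (camera adjusted p = 0.0203, lost with adjusted p = 0.262 with an estimated correlation). Vegfa, a hypoxia-inducible angiogenic factor, fell from 152 ± 14.9 to 43.6 ± 10.7 CPM. Mki67, expressed in dividing cells, stood at 0.17 (edgeR adjusted p = 0.813). Of 22 glycolysis and hypoxia genes 15 fell and 7 were not called (19 fell with p adjusted over the list alone), among them Pdk1 (-2.05 ± 0.23). Of 22 cholesterol synthesis genes 16 fell and 6 were not called (21 over the list alone), with Lss at -1.83 ± 0.26 and Hmgcs1, from 180 ± 23.98 to 62.8 ± 13.4 CPM. Of 20 lysosome genes 5 fell (7 over the list alone), with Ctsl at -1.32 ± 0.21. Of 27 type I interferon genes 9 rose (23 over the list alone), with a median of 1.27. Macrophage markers were lower in the treated libraries: 8 of 15 fell (14 over the list alone), with a median of -2.08, and C1qa went from 49.9 ± 16.96 to 9.23 ± 4.47 CPM. Endothelial markers had a median of -0.99 over 9 tested genes (-0.94 with genes without counts at their bound). Summed dissociation stress genes went from 2227 ± 482 to 1179 ± 160 CPM and erythroid markers from 530 ± 333 to 234 ± 178 CPM. Treated replicate 3 correlated with treated replicates 1 and 2 at a Spearman's rho of 0.966 and 0.962, beside 0.978 between those 2.

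edgeR called 225 genes higher and 298 lower in 2646TN at adjusted p under 0.05. The edgeR adjusted p was 2.35e-05 for Ogn, and for the others Acta2 2.43e-05, Vegfa 4.39e-10, Pdk1 9.71e-07, Lss 5.17e-05, Hmgcs1 8.60e-05, Ctsl 2.51e-04 and C1qa 0.00225. In camera the adjusted p was 1.32e-40 for glycolysis and hypoxia (0.00129 with an estimated correlation), 9.28e-34 for cholesterol synthesis (0.00562), 1.08e-06 for lysosome (0.0138), 8.80e-15 for macrophage markers (0.0195), 0.00152 for endothelial markers (0.0198) and 0.00282 for YAP and TEAD targets (0.0302), of which 2 of 12 rose. The type I interferon call, adjusted p = 3.88e-16 in camera, was lost with adjusted p = 0.0591 with an estimated correlation. The fibroblast call was also lost without untreated 2646TN replicate 3 (camera adjusted p = 0.162), treated replicate 1 (0.136) or treated replicate 2 (0.0834). With the macrophage marker mean as a covariate 268 genes were called, and the call of C1qa was lost (edgeR adjusted p = 0.798), as the setting entails for a gene that is part of that mean. Without untreated 2646TN replicate 1 the count was 240, without replicate 2 it was 285, and without treated 2646TN replicate 1 it was 329.

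In 2646R, RAFi/MEKi lowered stress, hypoxia and lysosome transcripts and raised cell division transcripts, though the list calls of the latter were lost with an estimated correlation. Ddit3, a transcription factor gene of the stress response, fell from 546 ± 92.1 to 47.3 ± 3.95 CPM (n = 3 each), and Trib3, its target, from 198 ± 30.4 to 4.94 ± 1.00. Mki67 rose from 71.6 ± 31.1 to 162 ± 8.25 CPM. Car6, a secreted carbonic anhydrase gene, fell from 69.9 ± 7.41 to 1.19 ± 0.325 CPM. Ogn (5.01 ± 0.78), Mfap4 (4.96 ± 0.80) and Inmt (4.88 ± 0.72) rose most. Sh2d6 fell by a ratio of 83.0 (95% interval 22.99 to 686). All 22 glycolysis and hypoxia genes fell, among them Vegfa, from 300 ± 25.9 to 62.2 ± 2.06 CPM. Of 19 ATF4 and unfolded protein response genes 14 fell and 5 were not called (16 over the list alone). Of 16 p53 targets 9 fell, with Cdkn1a at -2.18 ± 0.32, and of 20 lysosome genes 10 fell (12 over the list alone), with Sqstm1 at -1.84 ± 0.15. Of 24 mitosis genes 16 rose and 8 were not called (21 over the list alone), with Cdc20 at 1.30 ± 0.24. Of 23 DNA replication genes 13 rose (14 over the list alone). Cholesterol synthesis had a median of -0.57, with 6 of 22 genes lower (10 over the list alone). Of 15 macrophage markers 2 were called higher and 0 lower (median 1.13). Summed pericyte and smooth muscle markers went from 106 ± 40.9 to 766 ± 141 CPM (list not called, camera adjusted p = 0.0765) and fibroblast markers from 6569 ± 725 to 15897 ± 1075 CPM (camera adjusted p = 0.00467, lost with adjusted p = 0.240 with an estimated correlation).

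edgeR called 1289 genes higher and 1358 lower in 2646R at adjusted p under 0.05. Adjusted p in edgeR was 2.76e-09 for Ddit3, 9.08e-06 for Trib3, 8.11e-04 for Mki67, 9.83e-09 for Car6, 7.09e-05 for Ogn, 2.70e-05 for Sh2d6, 7.45e-13 for Vegfa, 4.41e-05 for Cdkn1a and 2.68e-10 for Sqstm1. The camera adjusted p was 3.03e-37 for glycolysis and hypoxia (0.00212 with an estimated correlation), 6.69e-14 for ATF4 and unfolded protein response (0.0101), 3.20e-05 for p53 targets (0.0101) and 8.56e-10 for lysosome (0.00231). Mitosis had 2.55e-10 in camera, lost with adjusted p = 0.103 with an estimated correlation, DNA replication 3.20e-05 (lost, 0.290) cholesterol synthesis 4.29e-04 (lost, 0.492) and macrophage markers 0.0287 (lost, 0.586). The macrophage call was also lost without untreated 2646R replicate 2 (camera adjusted p = 0.112) or treated 2646R replicate 1 (0.0574). With the macrophage marker mean as a covariate 1728 genes were called.

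In 14559TN, treated tumours had far lower cell division transcripts, lower cholesterol synthesis transcripts, and higher interferon transcripts, of which the interferon list calls were lost with an estimated correlation. Mki67 fell from 70.2 ± 9.93 to 7.12 ± 0.748 CPM and Ccnd1, which encodes cyclin D1, from 2393 ± 193 to 662 ± 114 CPM (n = 3 each). Etv4, a transcription factor gene downstream of ERK, fell from 113 ± 7.96 to 9.18 ± 4.00 CPM, while Spry2, an inhibitor of the same pathway, rose by 0.97 ± 0.15. All 24 mitosis genes fell (median -3.07), with Cenpf from 107 ± 13.2 to 10.3 ± 1.15 CPM. Of 23 DNA replication genes 20 fell and 3 were not called (21 over the list alone), with Mcm6 at -3.03 ± 0.25. All 22 cholesterol synthesis genes fell, with Cyp51 from 122 ± 14.98 to 12.3 ± 1.77 CPM. Among 27 type I interferon genes 26 rose (median 3.09, or 3.04 at the bound), with Stat2 from 33.0 ± 4.93 to 167 ± 7.55 CPM. Of 18 interferon gamma genes 16 rose (18 over the list alone), and 15 of 27 oxidative phosphorylation genes fell. Acta2 (4.33 ± 0.58), Postn (3.51 ± 0.60) and Col14a1 (5.81 ± 0.91) rose, and macrophage markers had a median of 0.60 (camera adjusted p = 0.282). Summed pericyte and smooth muscle markers went from 14.03 ± 3.03 to 154 ± 40.6 CPM, fibroblast markers from 9331 ± 479 to 13546 ± 3165 CPM and skeletal muscle markers from 9.06 ± 3.87 to 22.8 ± 6.44 CPM. Malat1 held 1.21 to 1.33% of the counts in untreated and 1.76 to 2.40% in treated 14559TN libraries, and ribosomal protein genes 2.55 to 2.91% and 1.74 to 1.86%. Genes named by size included Mrvi1, at least 24.9-fold higher, Folh1, higher by a ratio of 97.3 (17.5 to 3845), and Nuf2, lower by a ratio of 91.0 (16.3 to 3594).

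edgeR called 1647 genes higher and 2124 lower in 14559TN at adjusted p under 0.05. In edgeR the adjusted p was 2.93e-09 for Mki67, 7.82e-09 for Ccnd1, 3.43e-08 for Etv4, 5.66e-06 for Spry2, 1.33e-12 for Cenpf, 1.26e-10 for Mcm6, 3.04e-10 for Cyp51 and 2.80e-08 for Stat2. Camera gave an adjusted p of 1.06e-54 for mitosis (3.09e-04 with an estimated correlation), 1.69e-21 for DNA replication (0.0147) and 3.96e-27 for cholesterol synthesis (0.0147). Calls lost with an estimated correlation were type I interferon (camera 2.73e-23, then adjusted p = 0.0514), interferon gamma (4.59e-12, then 0.123), oxidative phosphorylation (9.49e-06, then 0.0558), pericyte and smooth muscle markers (0.0134, then 0.0558) and fibroblast markers (0.0475, then 0.316). Without untreated 14559TN replicate 2 or 3 or treated 14559TN replicate 2 the fibroblast call was lost as well (camera adjusted p = 0.0910, 0.0579 and 0.142), and with median-of-ratios size factors (0.0581).

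In 14559R few transcripts changed with RAFi/MEKi. Mki67 (-0.35, edgeR adjusted p = 0.668), Ccnd1 (-0.28, adjusted p = 0.626) and Etv4 (0.01, adjusted p = 1) were not called. The 26 called genes were 19 higher and 7 lower. They included the mitochondrial transfer RNA gene mt-Tp, from 18.3 ± 3.35 to 81.9 ± 23.7 CPM (n = 3 each, edgeR adjusted p = 0.0245), and Dtna, from 38.9 ± 7.24 to 18.1 ± 1.91 CPM (adjusted p = 0.0208). The share of all mitochondrial genes rose in the same libraries, from 0.063 to 0.074% of the counts untreated to 0.102 to 0.157% treated. A total of 1412 genes had an unadjusted p under 0.05, and DESeq2 called 113 genes. Over all genes 0 members of the mitosis list (24 tested), the DNA replication list (23) and the type I interferon list (27) were called, and 1 lower, 0 and 6 higher over the list alone. Their medians were -0.31, -0.34 and 0.93 (0.91 at the bound), with camera adjusted p = 8.12e-06, 8.12e-06 and 4.06e-09, all lost with adjusted p = 0.398 with an estimated correlation. Glycolysis and hypoxia had a median of -0.04 and a mean of the other sign (camera adjusted p = 0.972), and cholesterol synthesis a median of -0.21 (adjusted p = 0.0811).

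The 14559R calls depended on single libraries: 4 genes were called without untreated 14559R replicate 1, 53 without replicate 2, 6 without replicate 3, 13 without treated replicate 1, 13 without treated replicate 2 and 84 without treated replicate 3. The edgeR adjusted p of mt-Tp was 0.142 without untreated 14559R replicate 1, 0.115 without untreated replicate 3 and 0.0508 without treated replicate 1. For Dtna it was 0.0511 without untreated 14559R replicate 2, 0.0707 without untreated replicate 3, 0.0927 without treated replicate 1 and 0.0504 without treated replicate 2, and 0.0952 in a fit of only the groups compared. That fit called 3 genes, and a fit without the low-count filter called 319. The mitosis call was lost without untreated 14559R replicate 1 (camera adjusted p = 0.0881).

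In 13TN, treated tumours had far lower cell division transcripts. Mki67 fell from 80.8 ± 10.9 to 4.25 ± 1.07 CPM, Ccnd1 from 2985 ± 859 to 679 ± 121 CPM and Etv4 from 97.6 ± 24.2 to 19.1 ± 5.49 CPM (n = 3 each), while Spry4, an ERK pathway inhibitor, rose by 0.86 ± 0.24. All 24 mitosis genes fell (median -4.08), with Cenpf from 121 ± 10.97 to 5.59 ± 1.07 CPM, as did 20 of 23 DNA replication genes, with Cdt1 at -2.64 ± 0.20. Of 22 cholesterol synthesis genes 20 fell, with Cyp51 at -3.64 ± 0.28, and of 22 glycolysis and hypoxia genes 15 fell (16 over the list alone), with Car9 at -4.97 ± 0.41. Of 19 ATF4 and unfolded protein response genes 13 fell (14 over the list alone), with Psat1 at -3.66 ± 0.35. Of 27 type I interferon genes 24 rose (25 over the list alone), with Oas2 at 3.46 ± 0.44. MAPK output, the list of genes downstream of ERK, had 3 higher, 4 lower and 8 not called of 15, with a median of -0.03. Summed fibroblast markers went from 4070 ± 477 to 8750 ± 546 CPM, pericyte and smooth muscle markers from 10.5 ± 4.11 to 49.0 ± 21.5 CPM and skeletal muscle markers from 3.00 ± 2.13 to 19.2 ± 7.53 CPM. Malat1 held 1.22 to 1.32% of the counts in untreated and 2.71 to 3.50% in treated 13TN libraries, and ribosomal protein genes 2.62 to 2.88% and 1.89 to 1.91%. Genes named by size included Amy1, at least 25.2-fold higher, Gbp11 (5.78 ± 0.74) and Fancd2, lower by a ratio of 158 (28.3 to 6222).

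edgeR called 1809 genes higher and 2311 lower in 13TN at adjusted p under 0.05. By edgeR, adjusted p was 3.67e-11 for Mki67, 2.62e-10 for Ccnd1, 3.79e-06 for Etv4, 0.00668 for Spry4, 5.59e-15 for Cenpf, 4.59e-12 for Cdt1, 7.45e-11 for Cyp51, 4.32e-11 for Car9, 3.36e-08 for Psat1, 4.57e-07 for Oas2 and 9.18e-07 for Gbp11. By camera, adjusted p was 4.25e-76 for mitosis (3.58e-05 with an estimated correlation), 7.56e-28 for DNA replication (0.00410) and 0.526 for MAPK output. Calls lost with an estimated correlation were cholesterol synthesis (camera 4.28e-16, then adjusted p = 0.0669), glycolysis and hypoxia (4.62e-13, then 0.0669), ATF4 and unfolded protein response (7.35e-08, then 0.0669), type I interferon (4.05e-12, then 0.207) and fibroblast markers (0.0281, then 0.329). Without untreated or treated 13TN replicate 3 the fibroblast call was lost as well (camera adjusted p = 0.0928 and 0.0521).

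**Figure D2:**
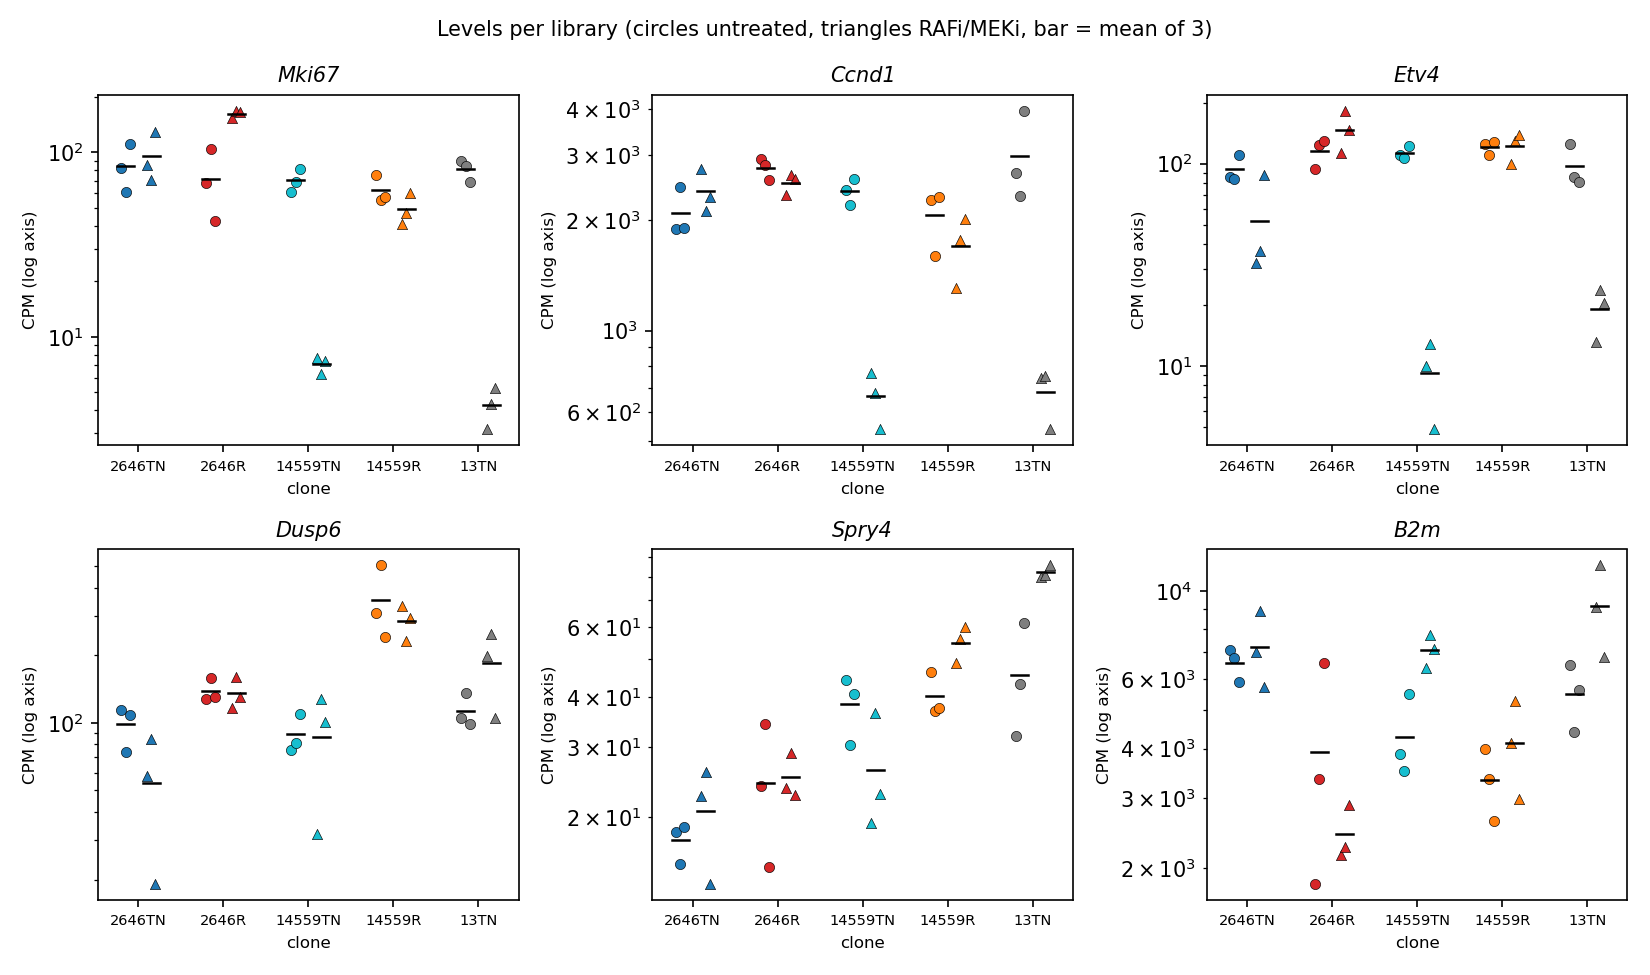
Levels of Mki67, Ccnd1, Etv4, Dusp6, Spry4 and B2m in CPM on a log axis, with 1 marker per library (circles untreated, triangles RAFi/MEKi) and a bar at the mean of 3. Mki67 fell in 14559TN (to 7.12 ± 0.748 CPM) and 13TN (to 4.25 ± 1.07) and rose in 2646R (to 162 ± 8.25).

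**Figure D3:**
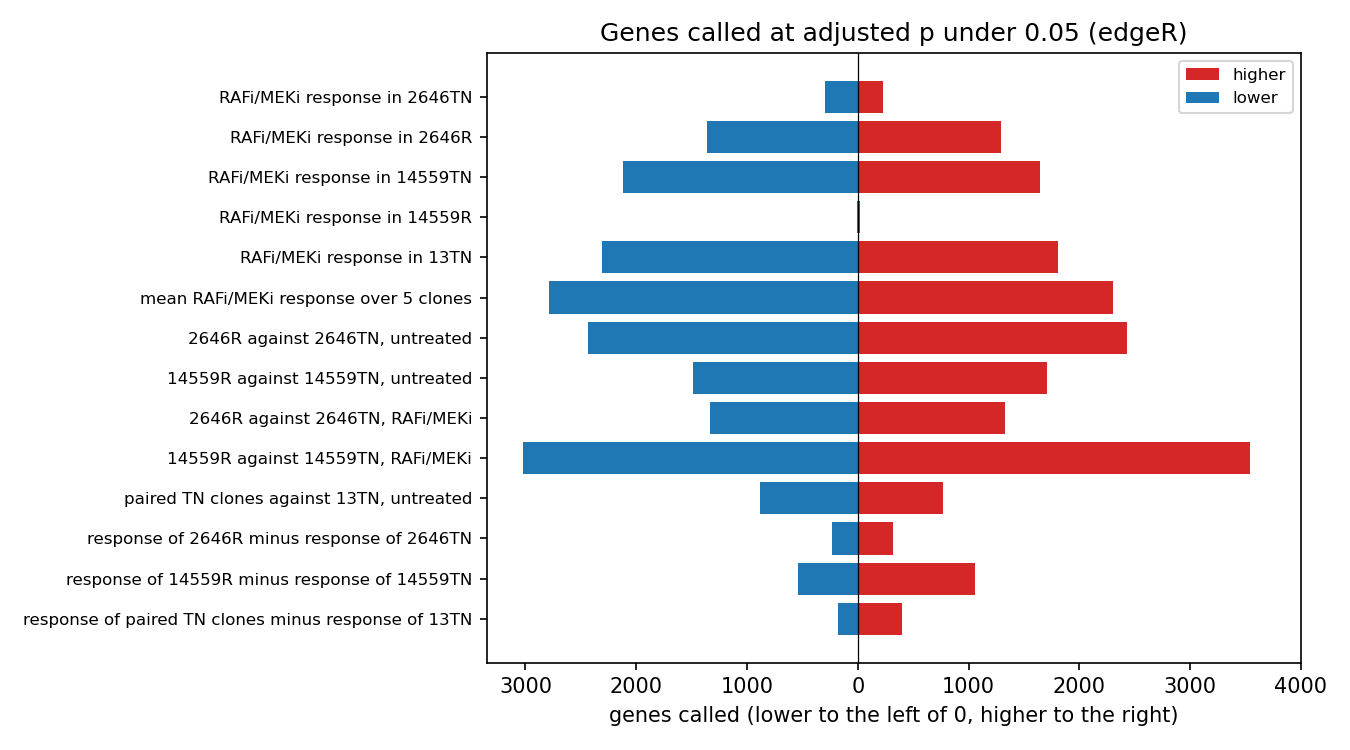
Number of genes called by edgeR in each of the 14 comparisons, lower to the left and higher to the right of 0. Counts ran from 26 genes for the response of 14559R to 6561 for 14559R against 14559TN under RAFi/MEKi.

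Averaged over the 5 clones, treated tumours had lower transcripts of cell division, cholesterol synthesis, glycolysis and hypoxia, and the unfolded protein response. The tests of this mean (n = 15 against 15) used the spread between tumours within a group. Their p-values and standard errors thus do not cover the spread between clones. The clones were unlike in division: summed mitosis genes went from 1338 ± 133 to 206 ± 35.2 CPM in 14559TN, 1907 ± 35.8 to 168 ± 21.6 in 13TN, 1860 ± 333 to 1436 ± 184 in 14559R, 1666 ± 249 to 1781 ± 361 in 2646TN and 1634 ± 337 to 2916 ± 212 in 2646R. Among single genes, Ogn rose by 4.21 ± 0.39, Ccdc3 by 3.38 ± 0.30, Acta2 by 3.11 ± 0.25 and Fbln5, an elastic fibre gene, by 3.08 ± 0.28. Car6 fell by 4.38 ± 0.34, Chrna1 by 3.76 ± 0.47 and Trib3 by 3.26 ± 0.33. Other large rises were in Oas2 (3.28 ± 0.59), Mfap4 (2.99 ± 0.37) and Myl9 (2.81 ± 0.36), and other large falls in Ibsp (-3.42 ± 0.71), Acsbg1 (-3.40 ± 0.48) and Slpi (-3.38 ± 0.74). edgeR called 2307 genes higher and 2792 lower at adjusted p under 0.05, with adjusted p = 8.16e-09 for Ogn, 2.01e-10 for Ccdc3, 2.68e-09 for Acta2, 8.81e-09 for Fbln5, 3.31e-11 for Car6, 1.85e-06 for Chrna1 and 7.88e-08 for Trib3. In GRCm38, Ogn (ENSMUSG00000021390) lies on chromosome 13 at 49608046 to 49624501, Acta2 (ENSMUSG00000035783) on chromosome 19 at 34241090 to 34255336 and Mki67 (ENSMUSG00000031004) on chromosome 7 at 135689784 to 135716361.

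Of the 29 lists tested as sets on the mean response, 7 were called with both correlations. On average mitosis fell in 24 of 24 genes (median -1.31, camera adjusted p = 2.28e-41, 0.00262 with an estimated correlation), DNA replication in 20 of 23 (-0.68, 4.57e-13, 0.0390), cholesterol synthesis in 22 of 22 (-1.23, 1.33e-31, 0.00539) and glycolysis and hypoxia in 21 of 22 (-1.19, 2.17e-32, 0.00296). ATF4 and unfolded protein response fell in 18 of 19 (-0.96, 8.67e-15, 0.00539), p53 targets in 11 of 16 with 1 higher (-0.49, 1.08e-04, 0.0147) and lysosome in 10 of 20 (-0.22, 2.25e-04, 0.0390). Examples were Kif23 (-1.47 ± 0.09), Cdt1 (-0.96 ± 0.08), Cyp51 (-1.90 ± 0.11), Ldha (-1.35 ± 0.07), Psat1 (-1.83 ± 0.15), Cdkn1a (-1.79 ± 0.15) and Ctsl (-1.40 ± 0.09). Over the list alone 22 glycolysis and hypoxia genes and 12 lysosome genes fell.

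A further set of lists was called by camera on the mean response only with the preset correlation. Type I interferon rose in 25 of 27 genes (median 1.50, adjusted p = 1.77e-19, then adjusted p = 0.0571 with an estimated correlation), interferon gamma in 15 of 18 (16 over the list alone; 1.25, 6.16e-08, then 0.211) and MHC class I presentation in 8 of 14 (9 over the list alone; 0.65, 1.40e-04, then 0.309). Fibroblast markers rose in 8 of 13 with 1 lower (0.83, 2.79e-04, then 0.103) and NF-kappaB and inflammatory genes in 7 of 16 with 2 lower (0.48, 0.0250, then 0.353). Oxidative phosphorylation fell in 11 of 27 (12 over the list alone; -0.16, 0.00489, then 0.202) and MAPK output in 6 of 15 with 1 higher (-0.11, 0.0167, then 0.120). The NF-kappaB call was lost without untreated 14559TN replicate 2 (camera adjusted p = 0.0567), treated 14559TN replicate 2 (0.0556), untreated 2646R replicate 1 (0.0507) or 2 (0.0513) or untreated 13TN replicate 1 (0.0517).

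The other lists were not called by camera on the mean response. As higher, lower, tested, median and adjusted p in camera these were RAF-MEK-ERK components 5, 8, 14, -0.19, 0.330, receptor tyrosine kinases and ligands 5, 5, 18, 0.09, 0.678, mesenchymal and invasive 3, 4, 17, -0.14, 0.293, neural crest and glial 2, 1, 8, 0.22, 0.697, and pigment cell differentiation 0, 1, 3, -0.88, 0.235. In the same order they were MHC class II presentation 2, 0, 8, 0.46, 0.108, BCL2 family 1, 3, 10, -0.10, 0.785 (the test pointed up), YAP and TEAD targets 2, 0, 12, 0.15, 0.308, Wnt beta-catenin targets 0, 2, 7, -0.29, 0.293, drug efflux transporters 2, 3, 6, -0.25, 0.734, and dissociation stress 3, 5, 13, -0.31, 0.650. Among markers of other cells they were macrophage 0, 3, 15, -0.27, 0.734, endothelial 1, 1, 9, -0.16, 0.445, pericyte and smooth muscle 2, 0, 4, 1.14, 0.0507, and erythroid 0, 0, 4, -0.74, 0.293. The 5 untested lists had summed levels of 1.17 to 7.88 CPM per group (neutrophil), 3.19 to 207 CPM (lymphocyte), 16.9 to 28.6 CPM (keratinocyte), 3.00 to 22.8 CPM (skeletal muscle) and 0 to 0.555 CPM (adipocyte). The highest lymphocyte sum, 207.46 CPM in untreated 2646R, was nearly all from 1 gene, Trbc2 (207.18 CPM).

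**Figure D4:**
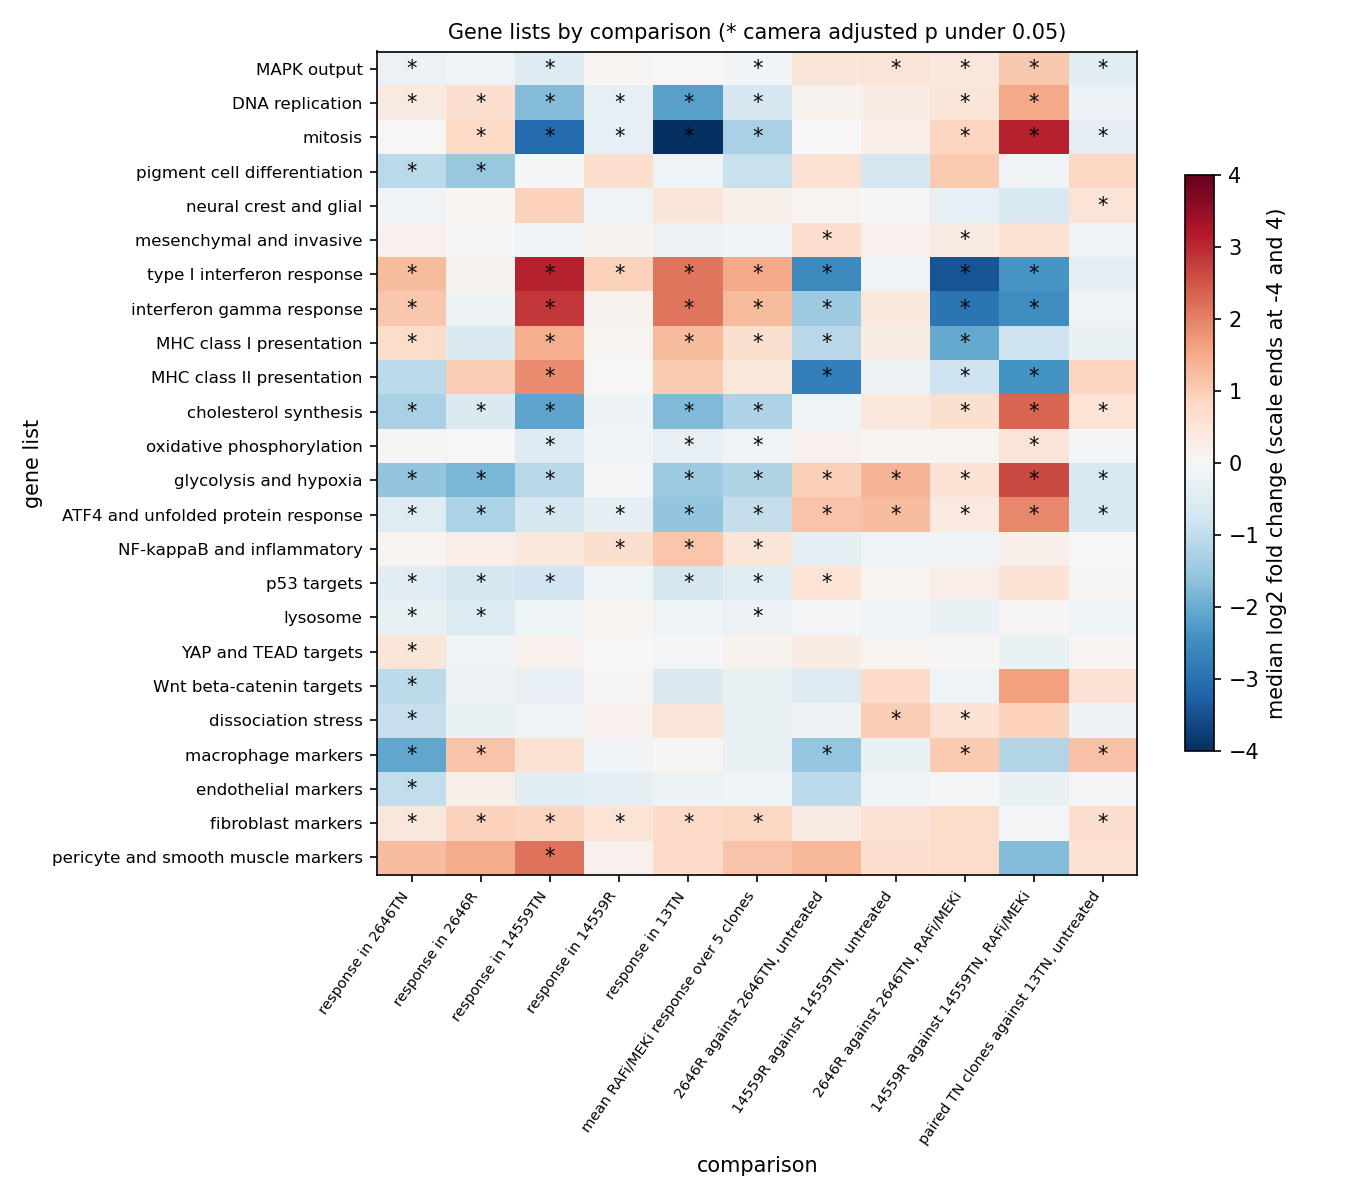
Median log2 fold change of the gene lists called in any of 11 comparisons (vertical), shown for each of these comparisons (horizontal). The colour scale is in log2 units, and a star marks a camera adjusted p under 0.05 with the preset correlation. Mitosis ran from -4.08 in the response of 13TN to 3.08 in 14559R against 14559TN under RAFi/MEKi.

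By count, most genes were shared between 14559TN and 13TN, the responses with the most calls, where 995 genes rose in both (224 for independent lists) and 1502 fell in both (369). In all 3 TN clones 88 genes rose (3.80 for independent lists) and 115 fell (8.29). Only 2 genes were called the same way in all 5 clones and 119 genes in 4 of 5, while over 400 genes were called in opposite directions in 2 clones. The count for all 5 clones was limited by 14559R, where 19 genes were called higher and 7 lower. These are counts of calls, so genes with the same sign that were not called are left out. The total of 203 genes shared by the TN clones depended on 2646TN libraries: it was 106, 123 and 134 without untreated 2646TN replicates 1, 2 and 3, and 135 without treated 2646TN replicate 1.

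The next question was how untreated 2646R differed from untreated 2646TN. The R tumours had lower interferon and MHC class II transcripts and higher hypoxia, stress and p53 target transcripts, though none of these list calls held with an estimated correlation. Pet2 was at 72.0 ± 23.6 CPM in 2646TN and 0 in 2646R, at least 302-fold lower, and Ptprf was lower by a ratio of 627 (113 to 24775). Mmp9, a matrix-degrading protease gene, was at 901 ± 468 CPM in 2646R and 9.11 ± 2.93 CPM in 2646TN (n = 3 each). Aldh1a1, a retinaldehyde dehydrogenase gene, was lower by a ratio of 232 (64.1 to 1912), Aldh1a7 at least 73.3-fold, and Rarb, a retinoic acid receptor gene, at least 32.0-fold. Ldb2 was at least 41.5-fold higher, Rbfox1 higher by a ratio of 263 (47.1 to 10369) and Tnnt2 by 6.98 ± 0.72. Among the 27 type I interferon genes 24 were lower (median -2.56), with Stat2 at 15.7 ± 5.65 against 79.2 ± 3.03 CPM, and all 8 MHC class II genes were lower (median -2.72), with Cd74 at -3.29 ± 0.50. Of 22 glycolysis and hypoxia genes 13 were higher (15 over the list alone), with Car9 at 3.19 ± 0.32, and of 19 ATF4 and unfolded protein response genes 15 (17 over the list alone), with Ddit3 at 2.39 ± 0.26. Of 16 p53 targets 9 were higher, with Cdkn1a at 2.21 ± 0.32. Macrophage markers were lower as well, 9 of 15 (10 over the list alone, median -1.55), with summed levels of 62.3 ± 19.1 CPM in 2646R and 260 ± 58.4 CPM in 2646TN. The marker C1qa was at 6.76 ± 5.03 CPM in 2646R and 49.9 ± 16.96 in 2646TN, and Cd74 at 6.14 ± 4.86 and 57.7 ± 26.0. Macrophages left among the sorted cells thus stay open as a source of the MHC class II difference.

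edgeR called 2431 genes higher and 2438 lower in untreated 2646R at adjusted p under 0.05. Adjusted p values from edgeR were 9.25e-12 for Pet2, 5.04e-10 for Ptprf, 3.83e-08 for Mmp9, 1.63e-08 for Aldh1a1, 2.98e-08 for Aldh1a7, 6.58e-06 for Rarb, 2.10e-07 for Ldb2, 3.58e-08 for Rbfox1, 1.12e-07 for Tnnt2, 7.09e-08 for Stat2, 1.79e-05 for Cd74, 5.19e-09 for Car9, 1.12e-07 for Ddit3 and 1.51e-05 for Cdkn1a. No list call held with an estimated correlation: type I interferon had a camera adjusted p = 2.26e-14 (then adjusted p = 0.158), MHC class II 2.99e-05 (0.158), glycolysis and hypoxia 1.20e-06 (0.228), ATF4 and unfolded protein response 4.85e-07 (0.143), p53 targets 0.00344 (0.143) and macrophage markers 8.08e-04 (0.361). With the macrophage marker mean as a covariate 2074 genes were called. Pet2 (ENSMUSG00000035395) lies on chromosome X at 89403848 to 89409689 and Ddit3 (ENSMUSG00000025408) on chromosome 10 at 127290774 to 127296288.

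Untreated 14559R differed from untreated 14559TN in hypoxia, stress and ERK output transcripts, which were higher in R, though the call of ERK output was lost with an estimated correlation. Scarf2, a scavenger receptor gene, was at 30.2 ± 11.9 CPM in 14559R and 0 in 14559TN, at least 113-fold higher. Ibsp, a bone matrix protein gene, was at 552 ± 449 against 1.205 ± 0.567 CPM and Stc1, a secreted glycoprotein gene, at 407.96 ± 235 against 2.56 ± 0.890 CPM (n = 3 each). Sox10, a neural crest and melanocyte transcription factor gene, was at 19.5 ± 28.0 against 0.102 ± 0.177 CPM, a ratio of 216 (38.8 to 8547). The 3 untreated 14559R libraries held 1.75, 5.09 and 51.8 CPM of it, so that replicate 3 carried most of this ratio. Atp2a3, a calcium pump gene, was at least 244-fold lower, Dapk1 at least 44.5-fold lower, Ppl lower by a ratio of 172 (30.8 to 6774) and Nrk by -5.41 ± 0.50. Dusp6, a phosphatase gene induced by ERK, was at 351 ± 136 against 88.7 ± 17.9 CPM. Of 15 MAPK output genes 8 were higher and 7 not called, with Phlda1 at 1.70 ± 0.15. Of 22 glycolysis and hypoxia genes 20 were higher (21 over the list alone), with Slc16a3 at 4.94 ± 0.60, and of 19 ATF4 and unfolded protein response genes 16 (17 over the list alone), with Slc7a11 at 3.16 ± 0.55. Type I interferon genes had 1 higher, 3 lower and 23 not called, with a median of -0.15. Dissociation stress genes were higher in 6 of 13 (8 over the list alone).

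edgeR called 1709 genes higher and 1490 lower in untreated 14559R at adjusted p under 0.05. Named genes had edgeR adjusted p of 1.56e-09 for Scarf2, 6.09e-08 for Ibsp, 1.93e-07 for Stc1, 5.27e-05 for Sox10, 1.73e-05 for Atp2a3, 1.29e-06 for Dapk1, 8.93e-09 for Nrk, 0.00249 for Dusp6, 1.39e-09 for Phlda1, 3.13e-07 for Slc16a3 and 2.11e-04 for Slc7a11. For lists, the camera adjusted p was 6.33e-20 for glycolysis and hypoxia (0.0465 with an estimated correlation), 1.22e-10 for ATF4 and unfolded protein response (0.0465) and 0.533 for type I interferon. MAPK output (0.00524) and dissociation stress (0.0119) were lost, with adjusted p = 0.137 and 0.928 with an estimated correlation. Scarf2 (ENSMUSG00000012017) lies on chromosome 16 at 17797282 to 17808293, Atp2a3 (ENSMUSG00000020788) on chromosome 11 at 72961169 to 72993044 and Ibsp (ENSMUSG00000029306) on chromosome 5 at 104299171 to 104311469.

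Of the genes called R against TN untreated, 783 were higher in both pairs (313 for independent lists), 592 were lower in both (273) and 212 went opposite ways. Under RAFi/MEKi 899 were higher in both (355 for independent lists), 792 were lower in both (304) and 166 went opposite ways.

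Under RAFi/MEKi, 2646R had lower interferon and MHC class I transcripts than 2646TN and higher division transcripts, of which only the interferon list call held with an estimated correlation. Oas2, an antiviral enzyme gene, was at 0.157 ± 0.137 against 20.05 ± 1.48 CPM, a ratio of 128 (35.6 to 1061, n = 3 each). Pet2 was lower by a ratio of 2602 (467 to 102780) and H2-Q6 at least 33.5-fold. Tshz3 was at least 88.3-fold higher and Rbfox1 at least 61.3-fold. B2m, the light chain gene of MHC class I, was lower by -1.57 ± 0.33, and Mitf, a pigment cell transcription factor gene, higher by 1.04 ± 0.26. Of 27 type I interferon genes 26 were lower (27 over the list alone, median -3.46), with Rsad2 at 3.21 ± 1.80 against 107 ± 13.1 CPM, and of 14 MHC class I genes 12 (13 over the list alone), with Tap1 at -3.20 ± 0.61. Of 24 mitosis genes 16 were higher (22 over the list alone), with Kif23 at 1.33 ± 0.18. Macrophage markers had a median of 1.04, with summed levels of 139 ± 13.97 CPM in 2646R and 58.2 ± 26.0 CPM in 2646TN.

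edgeR called 1333 genes higher and 1336 lower between the treated 2646 clones at adjusted p under 0.05. With edgeR the adjusted p was 1.45e-08 for Oas2, 2.91e-13 for Pet2, 2.65e-04 for H2-Q6, 1.69e-09 for Tshz3, 2.34e-07 for Rbfox1, 0.00146 for B2m, 0.00403 for Mitf, 1.57e-07 for Rsad2, 8.42e-04 for Tap1 and 1.79e-06 for Kif23. Type I interferon had a camera adjusted p = 4.04e-41 (0.0191 with an estimated correlation). MHC class I (1.68e-09), mitosis (2.00e-10) and macrophage markers (0.00732) were lost, with adjusted p = 0.167, 0.165 and 0.353 with an estimated correlation. The macrophage call was also lost without treated 2646TN replicate 2 (camera adjusted p = 0.0719). Oas2 (ENSMUSG00000032690) lies on chromosome 5 at 120730333 to 120749853.

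Under RAFi/MEKi, 14559R had far higher division, glycolysis and sterol transcripts than 14559TN and lower interferon transcripts, though the sterol and interferon list calls were lost with an estimated correlation. Ldha, a lactate dehydrogenase gene, was at 391 ± 81.5 against 41.1 ± 7.71 CPM and Cyp51 at 146 ± 32.3 against 12.3 ± 1.77 CPM (n = 3 each). Ibsp was higher by a ratio of 2890 (519 to 114140) and Il10, a cytokine gene, at least 106-fold. Tox was lower by a ratio of 729 (131 to 28806) and Arhgap20 at least 60.2-fold. All 24 mitosis genes were higher (median 3.08), with Kif23 at 3.55 ± 0.24, and so were all 22 glycolysis and hypoxia genes (median 2.65), with Car9 at 5.79 ± 0.46, and all 22 cholesterol synthesis genes (median 2.32). Of 15 MAPK output genes 10 were higher and 5 not called (11 over the list alone), with Fosl1 at 4.25 ± 0.39, Etv4 at 3.70 ± 0.35 and Dusp6 at 1.71 ± 0.44. Of the 27 type I interferon genes 22 were lower (24 over the list alone, median -2.37), with Stat2 at -2.33 ± 0.24. Summed pericyte and smooth muscle markers were at 34.1 ± 7.21 CPM in 14559R and 154 ± 40.6 in 14559TN. In the same order, erythroid markers were at 140 ± 48.8 and 38.1 ± 11.5 CPM and dissociation stress genes at 1971 ± 339 and 1164 ± 498 CPM. Ribosomal protein genes held 2.65 to 3.19% and 1.74 to 1.86% of the counts.

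edgeR called 3539 genes higher and 3022 lower between the treated 14559 clones at adjusted p under 0.05. Single genes had adjusted p in edgeR of 1.44e-15 for Ldha, 2.40e-11 for Cyp51, 3.64e-08 for Ibsp, 5.68e-07 for Il10, 5.18e-11 for Tox, 4.09e-06 for Arhgap20, 3.48e-13 for Kif23, 1.45e-11 for Car9, 5.66e-09 for Fosl1, 7.21e-09 for Etv4, 0.00297 for Dusp6 and 9.48e-09 for Stat2. Camera adjusted p came to 1.06e-30 for mitosis (0.00932 with an estimated correlation), 1.09e-24 for glycolysis and hypoxia (0.0127) and 2.33e-05 for MAPK output (0.0154). Cholesterol synthesis (7.27e-18) and type I interferon (5.47e-10) were lost, with adjusted p = 0.0538 and 0.228 with an estimated correlation.

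Untreated 2646TN and 14559TN, taken as a mean, differed from untreated 13TN (titled Depleted1) in glycolysis and stress transcripts, of which 10 of 22 and 7 of 19 list genes were lower in the paired TN clones and neither list call held with an estimated correlation. The 2 paired TN clones were unlike: summed glycolysis and hypoxia genes were at 5161 ± 401 CPM in 2646TN, 3601 ± 267 in 14559TN and 5510 ± 749 in 13TN, and ATF4 and unfolded protein response genes at 3619 ± 84.2, 2404 ± 210 and 3879 ± 337 CPM. Dusp2, a phosphatase gene, was at 7.19 ± 3.12 CPM in the 6 paired TN tumours and 88.4 ± 30.4 CPM in the 3 13TN tumours. Tmem121 was lower by a ratio of 128 (35.4 to 1057). Pet2 was at least 141-fold higher in the paired TN clones (37.6 ± 40.5 CPM over 6 tumours), a fold carried by 2646TN (72.0 ± 23.6 CPM). Also higher were Lefty1, a secreted inhibitor of nodal signals, at least 23.99-fold, and Slc4a3 by a ratio of 103 (35.3 to 501). Mitf was lower by -0.82 ± 0.20 (23.1 ± 2.89 CPM in 2646TN, 51.6 ± 0.835 in 14559TN and 60.7 ± 1.99 in 13TN). Of 22 glycolysis and hypoxia genes 10 were lower (11 over the list alone), with Car9 at -2.86 ± 0.27, and of 19 ATF4 and unfolded protein response genes 7 (9 over the list alone), with Slc3a2 at -1.11 ± 0.15. Of 24 mitosis genes 6 were lower (9 over the list alone), with Nusap1 at -0.85 ± 0.19. Fibroblast markers were higher in 3 of 13 (4 over the list alone), with Pdgfra at 1.24 ± 0.20, and macrophage markers had a median of 1.18 with 0 called over all genes and summed levels of 260 ± 58.4 CPM in 2646TN, 62.7 ± 35.5 in 14559TN and 64.0 ± 19.9 in 13TN.

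edgeR called 765 genes higher and 879 lower in the paired TN clones at adjusted p under 0.05. These tests used the spread between tumours within a group, so their p-values do not cover the spread between clones. The edgeR adjusted p came to 6.34e-08 for Dusp2, 1.17e-06 for Tmem121, 2.59e-08 for Pet2, 4.96e-06 for Lefty1, 8.41e-10 for Slc4a3, 0.00467 for Mitf, 4.56e-09 for Car9, 2.49e-06 for Slc3a2, 0.00206 for Nusap1 and 1.18e-04 for Pdgfra. No list call held with an estimated correlation: glycolysis and hypoxia had a camera adjusted p = 7.53e-09 (then adjusted p = 0.263), ATF4 and unfolded protein response 1.09e-04 (0.263), mitosis 1.09e-04 (0.584) and fibroblast markers 0.00152 (0.263). The macrophage markers had 0.00639 (0.675), and that call was lost without untreated 14559TN replicate 3 (camera adjusted p = 0.0646) or untreated 13TN replicate 2 (0.0587). With the macrophage marker mean as a covariate 1089 genes were called, and 779 were called without untreated 13TN replicate 3.

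The last question was whether responses differed between clones, tested as differences of the treatment effects. In the 2646 pair single genes differed in their response, and no list call held with an estimated correlation. Ddit3 differed by -2.63 ± 0.37 and Sqstm1, an autophagy receptor gene, by -1.51 ± 0.21, while Pappa differed by 9.31 ± 1.37. Of 15 macrophage markers 8 were higher (11 over the list alone, median 3.10), and of 24 mitosis genes 1 was higher (12 over the list alone, median 0.80), with Mki67 at 1.00 (edgeR adjusted p = 0.0922). edgeR called 314 genes higher and 237 lower, with adjusted p = 1.77e-04 for Ddit3, 3.33e-05 for Sqstm1 and 1.98e-04 for Pappa. The camera calls of macrophage markers (adjusted p = 4.71e-15) and mitosis (2.46e-09) were lost, with adjusted p = 0.0684 and 0.182 with an estimated correlation. With the macrophage marker mean as a covariate 47 genes were called, and without the low-count filter 977. The count was 362 without untreated 2646R replicate 1, 352 without treated 2646R replicate 1 and 831 without treated 2646TN replicate 3.

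In the 14559 pair the response of R was higher than that of TN for division and sterol genes and lower for interferon genes, of which the interferon list call was lost with an estimated correlation. Mki67 differed by 2.96 ± 0.39, Ccnd1 by 1.57 ± 0.26, and Etv4 by 3.61 ± 0.45. Klhl40 differed by 7.99 ± 1.51, Kcnk3, a potassium channel gene, by 6.03 ± 0.90, Col14a1, a collagen gene, by -8.59 ± 1.32 and Acta2 by -3.98 ± 0.81. Of 24 mitosis genes 23 were higher (24 over the list alone, median 2.86), of 23 DNA replication genes 16 (median 1.54), and of 22 cholesterol synthesis genes 17 (20 over the list alone, median 1.84), with Cyp51 at 3.04 ± 0.34. Among 27 type I interferon genes 8 were lower (18 over the list alone, median -2.16), with Ifih1, a viral RNA sensor gene, at -2.62 ± 0.47. edgeR called 1054 genes higher and 542 lower, with adjusted p = 6.25e-06 for Mki67, 8.36e-05 for Ccnd1, 6.25e-06 for Etv4, 4.32e-04 for Klhl40, 9.72e-05 for Kcnk3, 8.86e-05 for Col14a1, 0.00257 for Acta2, 8.56e-07 for Cyp51 and 4.21e-04 for Ifih1. With camera the adjusted p was 1.04e-50 for mitosis (4.13e-04 with an estimated correlation), 2.38e-15 for DNA replication (0.0396) and 6.70e-26 for cholesterol synthesis (0.0225). The type I interferon call (6.60e-12) was lost with adjusted p = 0.131 with an estimated correlation.

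The mean response of the paired TN clones differed from that of 13TN in division genes, whose fall was smaller in that mean. Summed mitosis genes did not fall in 2646TN (1666 ± 249 untreated, 1781 ± 361 CPM treated). They fell in 14559TN (1338 ± 133 to 206 ± 35.2 CPM) and in 13TN (1907 ± 35.8 to 168 ± 21.6 CPM). Mki67 differed by 2.68 ± 0.38, Ccnd1 by 1.31 ± 0.22, Fancd2, a DNA repair gene, by 5.40 ± 0.93 and Ect2, which acts in cytokinesis, by 4.23 ± 0.70. Prex2 differed by -3.66 ± 0.71. Of 24 mitosis genes 23 were higher (24 over the list alone, median 2.46), with Birc5 at 2.58 ± 0.24, and of 23 DNA replication genes 14 (19 over the list alone, median 1.41), with Rrm2 at 3.09 ± 0.44. Type I interferon genes had a median of 0.16 (camera adjusted p = 0.642) and cholesterol synthesis a median of 0.02, with a test pointing down (adjusted p = 0.934). This mean joined 2 unlike clones, since Mki67 stood at 0.17 in 2646TN and -3.31 in 14559TN. edgeR called 401 genes higher and 181 lower, with adjusted p = 4.05e-05 for Mki67, 3.14e-04 for Ccnd1, 3.15e-04 for Fancd2, 2.12e-04 for Ect2, 0.00129 for Prex2, 3.11e-08 for Birc5 and 2.57e-05 for Rrm2. List tests in camera gave adjusted p of 3.06e-64 for mitosis (8.48e-05 with an estimated correlation) and 5.70e-26 for DNA replication (0.00539). The count was 315 without untreated 13TN replicate 3, 339 without treated 13TN replicate 1 and 892 without the low-count filter.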

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

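All tests in this part except the splits were written after the results were seen. The bounds that decide each test were set at the same time, so they are descriptions of these data and no independent trial. The choice of these 3 patterns was also made after the results were seen.

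RAFi/MEKi moved 26 genes in 14559R and 3771 in 14559TN. Fewer reads did not account for this, since the mean total of the 14559R libraries was 1.15 times that of the 14559TN libraries. A greater spread alone would leave the size of the changes as it was, and the median change of the 4120 genes called in 13TN, signed by 13TN, was 0.12 in 14559R and 0.72 in 14559TN, a ratio of 0.170. That median was 0.09 in 2646TN and 0.23 in 2646R, with 523 and 2647 genes called, so it shows how far a response followed that of 13TN rather than its size. The median SD of log2 CPM within a group was 0.247 and 0.262 in untreated and treated 14559R, 0.199 and 0.229 in 14559TN, 0.249 and 0.229 in 13TN and 0.299 and 0.215 in 2646R. In 2646TN it was 0.230 and 0.317. The spread in 14559R was thus above that in 14559TN, and it could account for a part of the missing calls but not for the low ratio. A weak response and a response of another kind both stay open, and the exposure of these tumours to the drugs was not measured here. The count itself was unsettled: DESeq2 called 113 genes, a fit of only the groups compared 3, the fits that left out 1 library 4 to 84, and 1 other split of these libraries 155. That split exchanged untreated replicate 2 and treated replicate 3, so the count depended on where these 2 libraries were placed. On the first component treated replicate 3 lay at 43.9, within the untreated range (34.1 to 46.2). Untreated replicate 2 lay at the low end of that range. The count of 84 came without treated replicate 3. Why these 2 libraries stood apart from their groups was not tested.

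Macrophage markers fell with RAFi/MEKi in 2646TN, while in 2646R 2 of 15 were called higher and 0 lower (median 1.13, camera adjusted p = 0.0287, lost with adjusted p = 0.586 with an estimated correlation). A single library did not account for the difference of the responses under the preset correlation, since the highest adjusted p of the list in camera was 3.95e-12 when 1 of the 12 libraries was left out. With an estimated correlation the call of that difference was lost (camera adjusted p = 0.0684). Of the 15 tested markers, 12 had a lower treated level in 2646TN and a higher one in 2646R, but this count restates the pattern and decides nothing on its source. Macrophages left among the sorted cells stay open as untested. The labels name a sort for GFP after staining for CD45, and do not say whether CD45-positive cells were excluded. Expression of these genes by the tumour cells was not tested and could give the same values.

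Type I interferon genes were lower in 2646R than in 2646TN, untreated and treated. More macrophages in 2646TN could not account for the treated difference, where the macrophage markers were higher in 2646R by a median of 1.04. In the untreated tumours 21 of 27 members were still called lower with the macrophage marker mean as a covariate, with a median of -2.46 beside -2.56. The highest adjusted p of the list over the 12 fits that left out 1 library was 2.38e-11 (camera, preset correlation). With an estimated correlation the untreated call was lost (adjusted p = 0.158) and the treated one was kept (0.0191).

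For comparisons of 3 tumours with 3 the splits are too few for a share under 0.05. The real grouping was the only 1 of 10 splits to reach its count in 2646TN (523 genes, highest other 1), 2646R (2647, other 1), 14559TN (3771, other 0), 13TN (4120, other 1), 2646R against 2646TN untreated (4869, other 1) and treated (2669, other 1), and 14559R against 14559TN untreated (3199, other 0) and treated (6561, other 0). In 14559R 2 of 10 splits reached 26 genes, and the highest other split called 155.

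With 100 splits of the mean response, only the real grouping reached 5099 genes (highest other 3189). For the paired TN clones against 13TN, only the real grouping reached 1644 (highest other 1076). The first count speaks only against treatment labels without effect within the clones. The second speaks only against untreated libraries that are alike across these clones. Neither count tells how far other clones would differ. For the differences of responses the splits stand for no treatment effect within a clone, and not for equal effects in different clones. Their counts therefore cannot decide whether responses differed, and chance was not excluded. In the 2646 pair 10 splits reached 551 genes (highest other 2481). In the 14559 pair 9 reached 1596 (highest other 3306), and for TN minus 13TN 12 reached 582 (highest other 3285). The other splits that did so, 9, 8 and 11, all kept or mirrored the treatment labels of at least 1 clone, so that the response of 1 clone stood in them unchanged. Of the 77, 79 and 69 splits without such a clone 0 did so, with highest counts of 3, 1 and 0.

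In the 2646 pair the difference of responses had list medians of 0.80 for mitosis, -0.95 for type I interferon, -1.28 for interferon gamma, -1.09 for MHC class I, 1.85 for MHC class II, 0.72 for cholesterol synthesis, -0.29 for glycolysis and hypoxia, -0.67 for ATF4 and unfolded protein response, -0.30 for p53 targets, -0.35 for lysosome, 0.92 for Wnt beta-catenin targets, 1.05 for dissociation stress and 3.10 for macrophage markers. Single genes in it were Pappa 9.31, Aldh1a7 7.91, Moxd1 5.65, Ifi206 -5.26, Cdsn -5.17 and Serpina3f -5.15. Aldh1a7 was without counts in untreated 2646R, so the size of its value is uncertain.

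In the 14559 pair the medians were 0.36 for MAPK output, 1.54 for DNA replication, 2.86 for mitosis, -0.91 for neural crest and glial, 0.40 for mesenchymal and invasive, -2.16 for type I interferon, -2.47 for interferon gamma, -1.25 for MHC class I, -1.98 for MHC class II, 1.84 for cholesterol synthesis, 0.46 for oxidative phosphorylation, 1.07 for glycolysis and hypoxia, 0.72 for ATF4 and unfolded protein response and -2.26 for pericyte and smooth muscle markers. Single genes in it were Atp2a3 10.23, Klhl40 7.99, Kcnk3 6.03, Col14a1 -8.59, Cacnb4 -7.02, Sult1a1 -6.27, Mki67 2.96, Ccnd1 1.57 and Etv4 3.61. Atp2a3 was without counts in untreated 14559R, so the size of its value is uncertain.

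For the paired TN clones minus 13TN the medians were 1.41 for DNA replication, 2.46 for mitosis, 0.81 for ATF4 and unfolded protein response, -0.68 for NF-kappaB and inflammatory, -1.26 for dissociation stress and -0.77 for macrophage markers. Single genes in it were Fancd2 5.40, Anks1b 4.58, Ect2 4.23, Saa3 -5.86, Amy1 -5.78, Prex2 -3.66, Mki67 2.68, Ccnd1 1.31 and Spry4 -1.02. Amy1 was without counts in untreated 13TN, so the size of its value is uncertain.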

How the results depend on the processing

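The macrophage covariate and the leaving out of libraries for list tests and sharing were chosen only after the results were seen, and the other alternatives before. Counts moved by more than 1.5 times as follows, and the cause was not tested. In 2646TN (523 genes) 965 were called without the low-count filter and 268 with the macrophage covariate, and 240 to 448 when 1 library was left out (240 without untreated 2646TN replicate 1, 285 without replicate 2, 329 without treated replicate 1). In 2646R (2647) the covariate gave 1728. In 14559R (26) no filter gave 319, a fit of only the groups compared 3 and DESeq2 113, and leaving out 1 library gave 4, 53 and 6 (untreated replicates 1 to 3) and 13, 13 and 84 (treated replicates 1 to 3). In 2646R against 2646TN untreated (4869) the covariate gave 2074. In TN against 13TN (1644) the covariate gave 1089, and 779 were called without untreated 13TN replicate 3. In the 2646 difference of responses (551) no filter gave 977 and the covariate 47, with 362 without untreated 2646R replicate 1, 352 without treated 2646R replicate 1 and 831 without treated 2646TN replicate 3. In the difference for TN minus 13TN (582) no filter gave 892, with 315 without untreated 13TN replicate 3 and 339 without treated 13TN replicate 1. List calls went from 150 to 33 with an estimated correlation. Genes shared by the 3 TN clones (203) went to 106, 123 and 134 without untreated 2646TN replicates 1, 2 and 3 and to 135 without treated 2646TN replicate 1.

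Over all single libraries left out, counts were 1775 to 2630 in 2646R, 2762 to 3262 in 14559TN, 3015 to 3764 in 13TN, 4626 to 5205 for the mean response, 3739 to 4658 and 1785 to 2468 for 2646R against 2646TN untreated and treated, 2205 to 3004 and 5523 to 6229 for 14559R against 14559TN untreated and treated, 779 to 1478 for TN against 13TN, and 352 to 831, 1108 to 1743 and 315 to 591 for the differences of responses in the 2646 pair, the 14559 pair and TN minus 13TN. List calls were 145 to 156, genes shared by the TN clones 106 to 243, and genes shared by the pairs, R against TN untreated (1375), 967 to 1495. With the macrophage covariate the sign turned for C1qb, itself a part of that covariate, in the response of 2646TN (0.127, edgeR adjusted p = 0.916) and, in the 2646 difference of responses, for Ctss (-0.00327, edgeR adjusted p = 1) and Cd74 (-0.525, edgeR adjusted p = 0.829).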

Other observations

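The tests in this part were chosen only after the results were seen. Single matrix and contractile genes rose with RAFi/MEKi in some clones, and the fibroblast list, called on the mean response (camera adjusted p = 2.79e-04), was lost with an estimated correlation (adjusted p = 0.103). Ogn rose in 2646TN (5.87 ± 0.69) and 2646R (5.01 ± 0.78), Acta2 in 2646TN (4.81 ± 0.54) and 14559TN (4.33 ± 0.58), and Col1a1 in 2646R by 1.86 ± 0.36 (edgeR adjusted p = 9.46e-04). The clones given for Ogn and Acta2 are examples. Both genes were also named for the mean response, where the rule was the same sign of the change in all 5 clones. In 14559R the summed pericyte and smooth muscle markers stood at 31.6 ± 2.09 CPM untreated and 34.1 ± 7.21 CPM treated. Its summed fibroblast markers stood at 12040 ± 1766 CPM untreated and 16830 ± 4978 CPM treated. Pet2 was present in 2646TN (72.0 ± 23.6 CPM untreated, 198 ± 58.9 CPM treated) and stood at 0 in untreated 2646R and untreated 13TN.

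Trbc2, the gene of a T cell receptor constant region, was at 207 ± 58.4 CPM in untreated and 189 ± 13.7 CPM in treated 2646R tumours, and at 21.4 ± 6.09 and 17.6 ± 1.34 CPM in 2646TN. In 14559TN it went from 39.0 ± 5.39 to 1.44 ± 0.722 CPM and in 13TN from 23.5 ± 5.46 to 1.16 ± 1.61 CPM, while in 14559R it stood at 32.1 ± 5.80 untreated and 67.9 ± 21.0 CPM treated. It was the only lymphocyte marker that passed the low-count filter. The pigment genes Tyr, Tyrp1 and Dct had 0 counts in all groups.

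The difference between R and TN clones before treatment ran against the response of a TN clone of the other pair, with no library in common. Of 1822 genes called both in 2646R against 2646TN untreated and in the response of 14559TN, 1584 (86.9%) went opposite ways, beside 691 for independent lists, and Spearman's rho over all tested genes was -0.38. Of 263 genes called both in 14559R against 14559TN untreated and in the response of 2646TN, 222 (84.4%) went opposite ways, beside 63.6 for independent lists, with rho at -0.20. This is consistent with the hypothesis that R clones sit, before treatment, further along an axis that RAFi/MEKi moved the other way in TN clones. Whether treatment moved R clones back along it was not tested. On the first component 2646R libraries lay at 36.9 to 45.8 untreated and 17.7 to 21.4 treated (2647 genes called). Untreated 14559R libraries lay at 34.1 to 46.2 and treated ones at 22.8, 28.5 and 43.9 (26 genes called). Without the treated library at 43.9, replicate 3, 84 genes were called in 14559R. The bounds for these tests were set with the values in view, so a further pair of clones would be needed to test the hypothesis.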
